A study of Homo sapiens with 10 samples.

How the data were processed

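RNA of 10 libraries was measured: HEK293T cells with a TRE3G-GFP reporter, transfected with dCas12a-miniVPR as wildtype (dCas12aWT) or mutant (vgdCas12a) and with crTet or crLacZ, or not transfected, with 2 libraries in each of 5 groups. Per the labels, RNA was extracted with a column kit, libraries were made and sequenced by a company, and the authors aligned reads to hg19 with STAR 2.5.4b and counted them with HTSeq. The deposited files hold, for each library, integer counts for 28308 genes and, in a second file, FPKM values for 43683 genes, and 28123 symbols are in both. The authors' FPKM values were not stated to be scaled between libraries beyond the total.

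Both kinds of file were checked against each other before any comparison was run. In the deposited count files 80.35% to 81.68% of reads fell in no gene and 13.61% to 14.76% in genes, 4199819 to 5556514 reads per library, and common genes such as GAPDH had almost no counts. The FPKM values were found to be whole reads divided by gene length and by the total: whole reads were recovered for 31754 of the 31764 genes above 0 (99.97%), within 1e-05 reads. The totals behind them were 24827352 to 34473296 assigned reads. The test planned before the data were examined, edgeR on the deposited counts, was therefore replaced as the main test by limma on the deposited FPKM, and kept as an alternative for the number of calls. This change was made after the files had been seen. No coordinates are given, since the annotation at hand is of another genome build than the files, and gene positions were used only for names and for which genes neighbour each other. Mitochondrial genes were absent from the FPKM table (0 symbols).

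The main test was limma-trend 3.58.1 on log2 of TMM-scaled FPKM plus 0.1 in R 4.3.3, with 1 mean per group over all 10 libraries and 5 residual degrees of freedom. TMM factors, from edgeR 4.0.16 on the recovered reads, ran from 0.9316 to 1.0290. Genes were kept by filterByExpr on the recovered reads (18343 genes), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 8 comparisons were crTet against crLacZ with each activator, vgdCas12a against dCas12aWT with each crRNA, their interaction, the averages of each pair of comparisons, and the 4 transfected groups averaged against untransfected cells. Levels are means ± SD of FPKM as deposited.

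Gene lists were 23 lists of cell states and cell types fixed before the data were examined, with 649 of 654 symbols matched, 595 as listed and 54 by another name. They were tested with camera at a preset correlation of 0.01 on the same log2 values, where log2 CPM had been planned, with adjusted p over the lists of a comparison, and with an estimated correlation and with fry as alternatives. Members were counted as called over all genes and, separately, adjusted over the list alone. Genes were chosen for naming by a rule fixed before the data were examined. It took, among called genes with a mean of at least 2 CPM, the 8 largest rises and 8 largest falls (5 and 5 for the interaction and the averages). Symbols that begin with LOC, LINC, SNOR or MIR were passed over there. It also took up to 3 called members of each list that was called or had at least 3 called members, and RELA. The p65 domain of RELA is part of VPR. GFP, the reporter, was not in the rule as fixed but was added in every comparison, and counts of genes chosen by rule include it. Other genes named outside that rule, among them GAPDH, ACRBP and RPS6 in the check of the counts and some genes that rose with both activators, were chosen after their values were seen. Some genes chosen by the rule are not reported here, but stay in the counts.

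Alternatives planned before the data were examined, given in the form in which they were run, were DESeq2 size factors in place of TMM, FPKM as deposited without further scaling, no filter or a filter at 1 CPM in 2 libraries, a pseudocount of 1, a replicate block, only the libraries compared, a log2 fold change of at least 1, limma-voom and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. These were applied to the main test as it now stands. That test and the recovered reads came after the files had been seen, so the form of these alternatives did too. A library left alone in its group was then assumed to vary like the other groups. The planned edgeR test on the deposited counts (9494 genes tested) became an alternative after the files were seen. Chosen after seeing the data were edgeR on the recovered reads and a correction of each library for gene length and GC content. GC content was known for 16807 of 18343 genes (91.6%). The replicate numbers did not pair libraries across groups, with correlations of replicate differences from -0.099 to 0.053. Counting error alone did not explain the spread of replicates, with a chi-square per degree of freedom of 2.188 to 5.239.

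The procedure was tested on simulated data with 100 genes changed at each size among 18343. It recovered 59% of genes changed by 0.5 log2 and 93% of those changed by 1 log2, and 5 of its 157 calls (3.18%) were unchanged genes. The changed genes were drawn only from genes with higher mean read counts, so recovery in genes with few reads was not tested. A comparison without change gave 0 calls. Camera called a simulated list of 40 genes shifted by 0.5, and 0 of 20 unshifted lists. Genes were simulated independently of each other, so this does not test calls in lists whose members vary together. The estimated correlation of the cytosolic ribosomal proteins was 0.615. The simulated shift was also larger than the median of any list called between transfected groups. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Sequence reads were not used here.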

Results

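Transcript levels were measured by RNA sequencing in HEK293T cells, a human embryonic kidney line, that carried GFP under the tetracycline-responsive TRE3G promoter. The 10 libraries fell into 5 groups of 2. In 4 groups the cells were transfected with a nuclease-dead Cas12a fused to the activator miniVPR, either the wildtype protein (dCas12aWT) or a mutant (vgdCas12a), together with a crRNA against the reporter promoter (crTet) or a non-targeting one (crLacZ). The remaining group was not transfected. Transfected cells were kept in hygromycin at 500 µg/ml and puromycin at 2 µg/ml for 2 days, so transfection and selection cannot be separated here. The reads assigned to genes behind the FPKM values were 25143764 and 25219093 for dCas12aWT with crTet and 28869709 and 30080745 for dCas12aWT with crLacZ. They were 27993124 and 25564443 for vgdCas12a with crLacZ, 27573966 and 24827352 for vgdCas12a with crTet, and 33600863 and 34473296 for untransfected cells. Levels below are FPKM, mean ± SD over the n = 2 libraries of a group, and log2 fold changes are given ± SE. Adjusted p-values are from limma with the Benjamini-Hochberg correction over 18343 genes. They measure the spread between samples that the labels call duplicates, with no word on whether they are biological or technical. That spread is pooled over all 5 groups, though replicates differed most with vgdCas12a and crTet. The median absolute log2 difference of replicates was 0.1195 there and 0.08476 to 0.1003 in the other groups.

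Reporter RNA was the transcript that crTet was designed to raise, and it rose with both activators. GFP stood at 8.57 ± 0.856 FPKM in untransfected cells, at 9.94 ± 0.61 with dCas12aWT and crLacZ and at 12.6 ± 0.973 with vgdCas12a and crLacZ. With crTet it reached 3383 ± 70.4 FPKM with dCas12aWT, 340 times the crLacZ level, and 11550 ± 1370 with vgdCas12a, 917 times the crLacZ level. The log2 fold change was 8.39 ± 0.09 (adjusted p = 4.11e-10) with dCas12aWT and 9.86 ± 0.09 (adjusted p = 9.83e-11) with vgdCas12a. Between the activators, GFP was 3.41 times higher with vgdCas12a in crTet cells (log2 fold change 1.79 ± 0.09, adjusted p = 0.000106). In crLacZ cells the ratio was 1.27 and did not pass the test (log2 fold change 0.32 ± 0.09, adjusted p = 0.13). The interaction, the crTet effect with vgdCas12a over that with dCas12aWT, was 1.47 ± 0.13 (adjusted p = 0.00252). GFP took up to 1.0029% of the reads of a library.

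**Figure D1:**
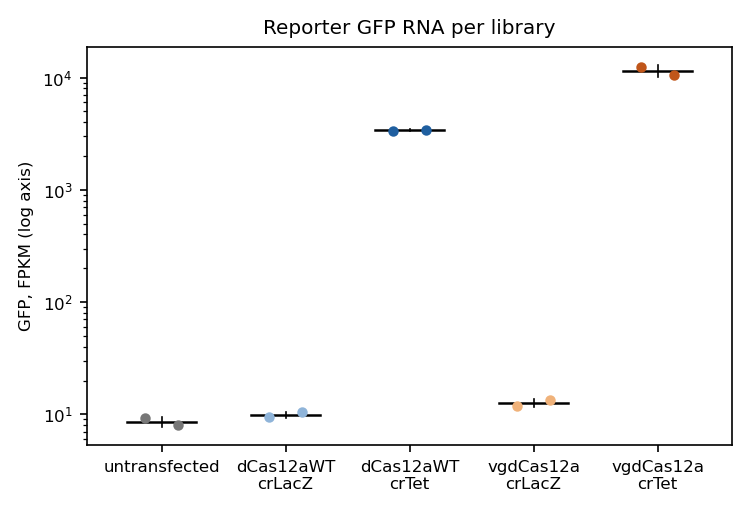
GFP RNA in FPKM on a log axis for the 10 libraries of the 5 groups. Points are libraries, horizontal bars the mean and vertical bars ± SD of 2 libraries, and both crTet groups (means 3383 and 11550) stand above the crLacZ and untransfected groups (means 8.57 to 12.6).

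With dCas12aWT, the crTet against crLacZ comparison asked which transcripts other than the reporter differed when the activator was given its target. Among the genes that the rule for naming allows, with a mean of at least 2 CPM, rises other than that of GFP were below 2-fold. RNU6-1, a U6 small nuclear RNA gene, went from 96.3 ± 12.8 to 171 ± 12.3 FPKM, and the histone gene H2BC21 from 8.38 ± 0.4 to 12.4 ± 0.1. RN7SL2, a 7SL RNA gene of the signal recognition particle, fell most among these genes, from 228 ± 26.2 to 93.8 ± 3.09 FPKM. SDR39U1 fell from 4.25 ± 0.14 to 2.04 ± 0.472, the ribosomal protein paralog RPL39L from 3.35 ± 0.0343 to 1.85 ± 0.235, and LSM6, part of the ring that binds U6 RNA, from 10.6 ± 0.328 to 7.01 ± 0.313. The log2 fold changes were 0.82 ± 0.11 for RNU6-1 (adjusted p = 0.0101), 0.55 ± 0.08 for H2BC21 (adjusted p = 0.0139), -1.29 ± 0.22 for RN7SL2 (adjusted p = 0.0206), -1.05 ± 0.15 for SDR39U1 (adjusted p = 0.0134), -0.84 ± 0.13 for RPL39L (adjusted p = 0.0151) and -0.59 ± 0.06 for LSM6 (adjusted p = 0.00579). RPL7P51, WHAMMP3, CREBRF, TAF1A-AS1 and RPS2P46 also rose, by log2 fold changes of 0.82 to 0.40, and RPS2P5, MATK, DUSP9 and CISD3 also fell, by -0.68 to -0.60. RNU6-1, RN7SL2 and the pseudogenes RPL7P51, RPS2P5 and RPS2P46 share sequence with other copies, and TAF1A-AS1 overlaps another gene, so their reads are uncertain in origin. RNU6-1 was not detected in untransfected cells, so whether its reads come from the endogenous gene or from transfected sequence is not known. RELA, whose p65 domain is part of VPR, had 41.7 ± 1.65 and 40.4 ± 0.405 FPKM (log2 fold change -0.06 ± 0.04, adjusted p = 0.491), and reads of the endogenous and the fused sequence are not told apart.

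In total 640 genes were called, 132 higher and 508 lower with crTet, and 16 rose and 9 fell by at least 2-fold. For each of the 640 the libraries of both groups did not overlap, against 53.6% of all tested genes. Without dCas12aWT crTet replicate 1 the count was 7, without its replicate 2 it was 103, without dCas12aWT crLacZ replicate 1 it was 41 and without its replicate 2 it was 13. Of the 44 called genes chosen by rule here, only GFP and RPS2P5 stayed called without each of these libraries. After correction for gene length and GC content 179 genes were called, 55 higher and 124 lower, and 20 of these 44 stayed called. Of the genes in the paragraph above, RPL7P51, WHAMMP3, CREBRF, TAF1A-AS1, MATK and DUSP9 did not.

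Of the gene lists in dCas12aWT cells, 8 were called at the preset correlation, most with few members called singly. None was called with an estimated correlation, and fry called 2, the G2/M and p53 target lists. In the G2/M and mitosis list 11 of 30 members rose, none fell and 19 did not pass. Counts were 22 and 0 adjusted over the list alone (camera adjusted p = 5.88e-16, adjusted p = 0.0616 with an estimated correlation). The mitotic kinase PLK1 went from 230.0 ± 2.07 to 270.0 ± 4.55 FPKM, the kinesin KIF18A from 29.9 ± 1.33 to 37 ± 1.5 and the kinetochore motor CENPE from 38.5 ± 0.847 to 48.2 ± 0.822. Among p53 targets 5 of 28 rose and 0 fell. Counts were 10 and 0 adjusted over the list alone (camera adjusted p = 7.88e-06, adjusted p = 0.0616 with an estimated correlation). BTG2 went from 75.6 ± 0.51 to 91.4 ± 1.09 FPKM, the death receptor FAS from 12.6 ± 0.902 to 16.7 ± 0.564 and the phosphatase PPM1D from 45.2 ± 0.11 to 54.4 ± 0.798. Of the 25 replication-dependent histones tested 2 rose, H2BC21 and H2BC12, and 0 fell. Counts were 6 and 0 adjusted over the list alone (camera adjusted p = 0.000701, adjusted p = 0.583 with an estimated correlation), and this list was not called without dCas12aWT crLacZ replicate 2. KIF18A and CENPE were not called after the correction for gene length and GC content.

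Of 77 cytosolic ribosomal proteins 5 fell and 0 rose. Counts were 10 and 0 adjusted over the list alone (camera adjusted p = 2.13e-07, adjusted p = 0.802 with an estimated correlation). RPS9 went from 198 ± 3.99 to 167 ± 0.204 FPKM and RPS28 from 129 ± 4.38 to 109 ± 3.13. Of 36 ribosome biogenesis factors 6 fell and 0 rose. Counts were 9 and 0 adjusted over the list alone (camera adjusted p = 3.08e-05, adjusted p = 0.629 with an estimated correlation), with NHP2 going from 79.6 ± 3.6 to 57.5 ± 1.92 FPKM. Of 45 nuclear-encoded respiratory chain genes 4 fell and 0 rose. Counts were 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000161, adjusted p = 0.651 with an estimated correlation). The cytochrome CYC1 went from 160.0 ± 2.38 to 129 ± 1.52 FPKM and NDUFA8 of complex I from 66.9 ± 1.67 to 52.7 ± 0.573. Of 31 glycolysis and hypoxia genes 4 fell and 0 rose. Counts were 11 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00782, adjusted p = 0.802 with an estimated correlation), among them NDRG1 from 13 ± 0.0522 to 9.85 ± 0.0447 FPKM. Of 31 genes of G1/S and DNA replication 5 fell and 0 rose. Counts were 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00202, adjusted p = 0.629 with an estimated correlation), including CHAF1B from 24 ± 0.378 to 20.8 ± 0.314 FPKM. Members of uncalled lists also fell: SDF2L1, CRELD2 and CALR of the unfolded protein response, and MVD and EBP of cholesterol synthesis, with log2 fold changes between -0.48 and -0.17. Of the former list 3 fell and 0 rose, and of the latter 3 fell and 1 rose. None of these 5 named genes, nor CYC1, RPS9 and RPS28, was called after the correction for gene length and GC content.

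With vgdCas12a, the same comparison gave larger changes in single genes. IGSF10, an immunoglobulin superfamily gene, rose from 0.0898 ± 0.00281 to 5.15 ± 0.927 FPKM with crTet, the ephrin ligand EFNB3 from 2.11 ± 0.177 to 36 ± 6.5, the phospholipase PLCD4 from 0.122 ± 0.0249 to 2.98 ± 0.12 and the interferon-induced gene IFI44L from 0.152 ± 0.0774 to 1.95 ± 0.205. Other genes were lower with crTet than with crLacZ. The sphingosine-1-phosphate receptor S1PR1 stood at 0.365 ± 0.02 against 6.04 ± 0.304 FPKM. The urokinase receptor PLAUR stood at 3.44 ± 0.0771 against 11.4 ± 0.6 and the ETS factor ETV1 at 0.227 ± 0.0131 against 1.17 ± 0.115. All of these were highest with vgdCas12a and crLacZ among the 5 groups. In dCas12aWT cells S1PR1 had 0.391 ± 0.0782 FPKM with crLacZ and 0.436 ± 0.0107 with crTet, so its vgdCas12a crLacZ level stood apart. Log2 fold changes were 4.79 ± 0.21 for IGSF10 (adjusted p = 1.54e-05), 4.05 ± 0.15 for EFNB3 (adjusted p = 7.11e-06), 3.81 ± 0.25 for PLCD4 (adjusted p = 0.000301) and 3.07 ± 0.25 for IFI44L (adjusted p = 0.000555). They were -3.69 ± 0.16 for S1PR1 (adjusted p = 1.54e-05), -1.67 ± 0.07 for PLAUR (adjusted p = 1.54e-05) and -1.92 ± 0.18 for ETV1 (adjusted p = 0.00121). VGLL2, CCDC80 and FAM124A rose by log2 fold changes of 2.94, 2.87 and 2.37, and NCAM2, KLHL14, MALINC1, PRDM8 and RTN4RL1 fell by -1.72 to -1.43. RELA had 44.2 ± 0.525 and 38.9 ± 1.78 FPKM (log2 fold change -0.15 ± 0.04, adjusted p = 0.0747). The 0.1 FPKM added before the logarithm makes these fold changes of low genes smaller than the ratios of their levels.

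In total 783 genes were called, 488 higher and 295 lower with crTet, and 89 rose and 29 fell by at least 2-fold. With the FPKM values as deposited, without TMM scaling, the split was 383 higher and 508 lower. For each of the 783 the libraries of both groups did not overlap, against 50.1% of all tested genes. The count was 150 without vgdCas12a crLacZ replicate 1, 191 without its replicate 2, 521 without vgdCas12a crTet replicate 1 and 384 without its replicate 2. Of the 41 called genes chosen by rule, 18 stayed called without each of these libraries: GFP, IGSF10, EFNB3, PLCD4, IFI44L, IFI44, VGLL2, CCDC80, FAM124A, SPARC, S1PR1, ETV1, NCAM2, KLHL14, PLAUR, MALINC1, PRDM8 and RTN4RL1.

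In gene lists, mitotic and p53 genes stood higher with crTet. Of 30 G2/M and mitosis genes 11 rose and 0 fell. Counts were 20 and 0 adjusted over the list alone (camera adjusted p = 4.15e-13, and adjusted p = 0.0498 with an estimated correlation). Survivin, BIRC5, went from 216 ± 4.38 to 249 ± 4.29 FPKM and CDC20 from 277 ± 0.756 to 317 ± 2.25. Of 28 p53 targets 9 rose and 0 fell. Counts were 14 and 0 adjusted over the list alone (camera adjusted p = 8.11e-09, and adjusted p = 0.0449 with an estimated correlation). PPM1D went from 52.4 ± 1.29 to 63.2 ± 2.3 FPKM, PHLDA3 from 94.6 ± 0.993 to 114 ± 1.95 and the repair gene DDB2 from 116 ± 3.92 to 134 ± 2.84. Of 25 replication-dependent histones 3 rose and 0 fell. Counts were 6 and 0 adjusted over the list alone (camera adjusted p = 5.14e-05, adjusted p = 0.28 with an estimated correlation). Of 36 ribosome biogenesis factors 2 rose and 0 fell. Counts were 18 and 0 adjusted over the list alone (camera adjusted p = 4.56e-08, adjusted p = 0.343 with an estimated correlation). Of 31 genes of G1/S and DNA replication 4 rose and 0 fell. Counts were 9 and 0 adjusted over the list alone (camera adjusted p = 2.13e-05, adjusted p = 0.343 with an estimated correlation), with the cyclin CCNE2 going from 7.32 ± 0.0744 to 9.47 ± 0.136 FPKM. Of 77 cytosolic ribosomal proteins 1 rose, RPLP2, and 0 fell, and none passed when adjusted over the list alone (camera adjusted p = 3.93e-05, adjusted p = 0.605 with an estimated correlation). RPLP2 was not called after the correction for gene length and GC content.

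Of 11 fibroblast and mesenchymal markers 3 rose and 0 fell. Counts were 4 and 0 adjusted over the list alone (camera adjusted p = 0.0017, adjusted p = 0.119 with an estimated correlation). They were the matrix gene SPARC, from 3.8 ± 0.33 to 7.75 ± 1.33 FPKM, the growth factor receptor PDGFRB, from 3.23 ± 0.0265 to 5.35 ± 0.488, and the collagen COL1A1, from 3.76 ± 0.138 to 5.3 ± 0.762. Of 26 genes of the unfolded protein response 3 fell and 0 rose. Counts were 6 and 0 adjusted over the list alone (camera adjusted p = 0.00117, adjusted p = 0.533 with an estimated correlation), among them the chaperone HSPA5, from 111 ± 0.807 to 92.7 ± 3.95 FPKM. Of 27 immediate early genes 1 rose, SRF, and 1 fell, JUNB. Counts were 3 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.0361 toward lower, adjusted p = 0.553 with an estimated correlation). Among 31 interferon-stimulated genes 2 rose, IFI44L and IFI44, and 2 fell. The list was not called (camera adjusted p = 0.0727), and its median of -0.15 and mean of 0.05 differed in sign. Without vgdCas12a crLacZ replicate 1 and without vgdCas12a crTet replicate 1 the ribosomal proteins and immediate early genes were not called, and without vgdCas12a crTet replicate 2 the immediate early genes and the unfolded protein response were not.

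**Figure D2:**
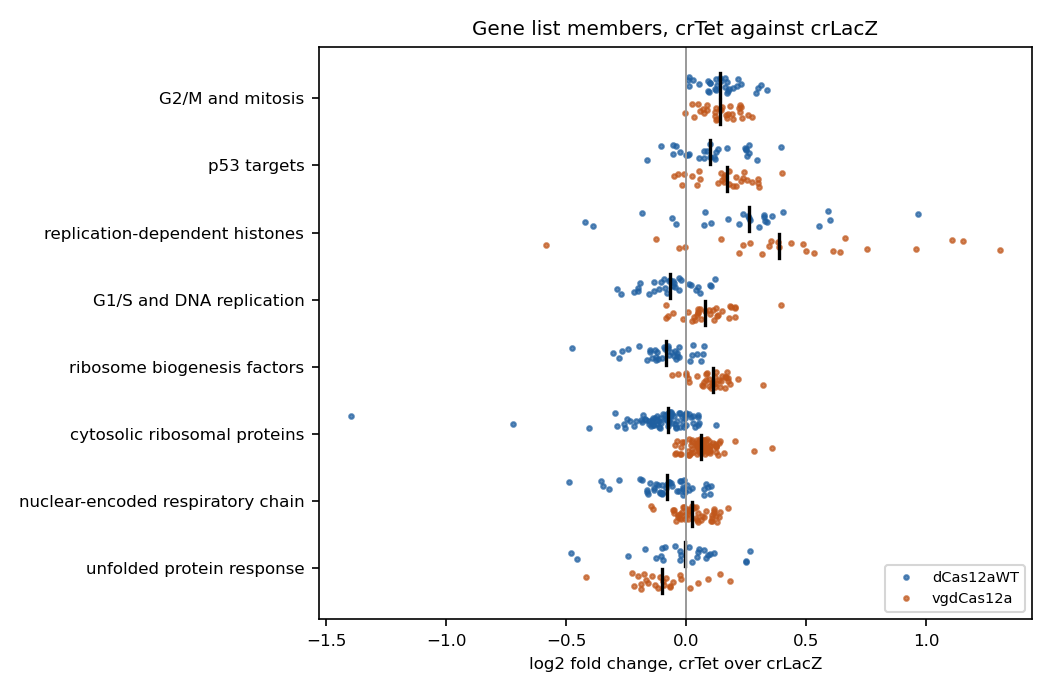
Log2 fold changes of the members of 8 gene lists, crTet over crLacZ, with dCas12aWT (blue) and with vgdCas12a (orange). Each point is a gene and each black bar the median of a list, and the G2/M and mitosis medians are 0.14 with both activators while those of ribosome biogenesis factors are -0.08 and 0.11.

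In crLacZ cells, the comparison of vgdCas12a with dCas12aWT asked how the mutant activator differed without a target in the reporter. S1PR1 was higher with vgdCas12a, at 6.04 ± 0.304 against 0.391 ± 0.0782 FPKM, as were FAM167A, at 4.8 ± 0.503 against 1.16 ± 0.161, PLAUR, at 11.4 ± 0.6 against 3.96 ± 0.00354, and the gap junction gene GJA1, at 32.5 ± 0.809 against 11.4 ± 0.472. The transcription factor MYC was lower, at 3.18 ± 0.0344 against 5.09 ± 0.132 FPKM, and BATF3 at 3.81 ± 0.293 against 6.12 ± 0.666. Log2 fold changes were 3.63 ± 0.16 for S1PR1 (adjusted p = 6.63e-05), 1.94 ± 0.15 for FAM167A (adjusted p = 0.0016), 1.49 ± 0.07 for PLAUR (adjusted p = 6.63e-05), 1.48 ± 0.07 for GJA1 (adjusted p = 6.63e-05), -0.68 ± 0.07 for MYC (adjusted p = 0.00632) and -0.68 ± 0.09 for BATF3 (adjusted p = 0.018). ETV1, LHX8, ZDHHC22 and MALINC1 were also higher, by 1.66 to 1.53, and TESC, CHCHD10, SLC27A2, E2F5, GAS1 and F12 lower, by -0.68 to -0.47. CHCHD10 and F12 were not called after the correction for gene length and GC content. RELA differed by 0.07 ± 0.04 (adjusted p = 0.449). In total 241 genes were called, 147 higher and 94 lower, and 28 were higher and 1 lower by at least 2-fold. With DESeq2 on recovered reads the split was 455 and 445. For each of the 241 the libraries of both groups did not overlap, against 51.7% of all tested genes. The count fell to 7 without either dCas12aWT crLacZ replicate 1 or 2, to 7 without vgdCas12a crLacZ replicate 1 and to 8 without its replicate 2, and FAM167A, GJA1, MALINC1, PLAUR, S1PR1 and ZDHHC22 stayed called without each of them.

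Of the gene lists in crLacZ cells, p53 targets had 3 of 28 members higher with vgdCas12a and 0 lower. Counts were 7 and 0 adjusted over the list alone (camera adjusted p = 6.17e-08, adjusted p = 0.0627 with an estimated correlation). BTG2 stood at 98.4 ± 0.12 against 75.6 ± 0.51 FPKM and the cell cycle inhibitor CDKN1A at 152 ± 0.731 against 122 ± 1.41. Interferon-stimulated genes had 1 of 31 higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00269, adjusted p = 0.204 with an estimated correlation). Immediate early genes had JUNB higher and MYC lower among 27. Counts were 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00588 toward higher, adjusted p = 0.379 with an estimated correlation). Of 18 apoptosis genes 1 was higher and 0 lower. Counts were 3 and 1 adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.204 with an estimated correlation). Toward lower, ribosome biogenesis factors had GNL3 alone of 36 lower. Counts were 8 adjusted over the list alone (camera adjusted p = 2.29e-09, adjusted p = 0.204 with an estimated correlation). None of 77 cytosolic ribosomal proteins passed singly, nor when adjusted over the list alone (camera adjusted p = 1.47e-08 toward lower, adjusted p = 0.581 with an estimated correlation). G1/S and DNA replication had 0 of 31 called. Counts were 12 lower adjusted over the list alone (camera adjusted p = 6.17e-08, adjusted p = 0.204 with an estimated correlation). Respiratory chain genes had UQCRC1 and UQCRC2 of 45 lower, also when adjusted over the list alone (camera adjusted p = 0.00208, adjusted p = 0.581 with an estimated correlation). Cholesterol synthesis had INSIG1 of 25 lower. Counts were 2 adjusted over the list alone (camera adjusted p = 0.0466, adjusted p = 0.204 with an estimated correlation). The neuronal and adrenal genes had 0 of 13 called. Counts were 1 lower adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.204 with an estimated correlation). Without vgdCas12a crLacZ replicate 1 the apoptosis, cholesterol, ribosomal protein, neuronal and respiratory chain lists were not called, nor were cholesterol synthesis without dCas12aWT crLacZ replicate 1 and the neuronal list without its replicate 2.

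In crTet cells, the comparison of vgdCas12a with dCas12aWT gave the most calls among the transfected groups in the main test, though not with only the libraries compared. IGSF10 stood at 5.15 ± 0.927 FPKM with vgdCas12a against 0.0488 ± 0.0124 with dCas12aWT, EFNB3 at 36 ± 6.5 against 2.8 ± 0.492, PLCD4 at 2.98 ± 0.12 against 0.0963 ± 0.0634, CCDC80 at 2.94 ± 0.776 against 0.182 ± 0.0202 and VGLL2, a transcription cofactor, at 3.59 ± 0.883 against 0.338 ± 0.0496. Lower with vgdCas12a were G0S2, an inhibitor of lipolysis, at 0.984 ± 0.104 against 2.45 ± 0.326 FPKM, and the Wnt ligand WNT3A, at 0.384 ± 0.0465 against 0.742 ± 0.0391. Log2 fold changes were 5.14 ± 0.21 for IGSF10 (adjusted p = 2.1e-05), 3.67 ± 0.15 for EFNB3 (adjusted p = 2.1e-05), 4.02 ± 0.25 for PLCD4 (adjusted p = 0.000215), 3.42 ± 0.24 for CCDC80 (adjusted p = 0.000215), 3.08 ± 0.22 for VGLL2 (adjusted p = 0.00022), -1.20 ± 0.18 for G0S2 (adjusted p = 0.00719) and -0.78 ± 0.17 for WNT3A (adjusted p = 0.029). IFI44L, TCHH and SEMA3D were higher by 3.24, 2.18 and 2.15, and ATP1B2, CAPS2, FZD10, FAM160B1, SLC46A3 and RBM11 lower by -0.91 to -0.62. All the lower genes named here but SLC46A3 lost their call without some single library. RELA differed by -0.03 ± 0.04 (adjusted p = 0.735). In total 1421 genes were called, 1050 higher and 371 lower, with 138 higher and 12 lower by at least 2-fold, and with FPKM as deposited the split was 828 and 578. For each of the 1421 the libraries of both groups did not overlap, against 51.2% of all tested genes. The count was 338 without dCas12aWT crTet replicate 1, 546 without its replicate 2, 756 without vgdCas12a crTet replicate 1 and 936 without its replicate 2, and 23 of the 52 called genes chosen by rule stayed called without each of them.

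Of 28 p53 targets 12 were higher with vgdCas12a in crTet cells and 0 lower. Counts were 14 and 0 adjusted over the list alone (camera adjusted p = 5.61e-07, adjusted p = 0.0699 with an estimated correlation). PHLDA3 stood at 114 ± 1.95 against 81.2 ± 4.4 FPKM and the stress gene GADD45A at 279 ± 11.1 against 216 ± 1.91. Of 11 fibroblast and mesenchymal markers SPARC, COL1A1 and COL5A1 were higher and 0 lower. Counts were 4 and 0 adjusted over the list alone (camera adjusted p = 0.00621, adjusted p = 0.215 with an estimated correlation), with SPARC at 7.75 ± 1.33 against 1.96 ± 0.102 FPKM. Of 10 epithelial markers 2 were also higher and 0 lower, with a median of 0.25. Camera did not call that list (camera adjusted p = 0.189, fry adjusted p = 0.0129). Of 36 ribosome biogenesis factors 5 were higher and 0 lower. Counts were 10 and 0 adjusted over the list alone (camera adjusted p = 0.000441, adjusted p = 0.76 with an estimated correlation), including BYSL at 75.8 ± 3.54 against 63.5 ± 0.454 FPKM. Of 77 cytosolic ribosomal proteins 10 were higher and 0 lower. Counts were 14 and 0 adjusted over the list alone (camera adjusted p = 0.000761, adjusted p = 0.819 with an estimated correlation). Of 45 respiratory chain genes 5 were higher and 2 lower. Counts were 9 and 2 adjusted over the list alone (camera adjusted p = 0.00686 toward higher, adjusted p = 0.819 with an estimated correlation). Of 31 genes of G1/S and DNA replication 5 were higher and 0 lower. Counts were 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0217 toward higher, adjusted p = 0.76 with an estimated correlation), and this list was not called with DESeq2 size factors. Among 31 interferon-stimulated genes 5 were higher and 2 lower, including IFI44 at 0.644 ± 0.186 against 0.023 ± 4.86e-05 FPKM and IFITM1 at 16.9 ± 2.99 against 7.79 ± 2.09, and the list was not called (camera adjusted p = 0.441). PDIA3, HSP90B1 and SEL1L of the unfolded protein response were lower by -0.34, -0.26 and -0.30, in a list that was not called (camera adjusted p = 0.0751). In that list 1 member was higher and 4 were lower. Without dCas12aWT crTet replicate 2 the G1/S list was not called, without vgdCas12a crTet replicate 1 the ribosomal proteins and respiratory chain were not, and without its replicate 2 the G1/S and ribosome biogenesis lists were not.

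The interaction asked whether the crTet effect differed between the activators, gene by gene. The crTet effect on IGSF10, EFNB3, PLCD4, IFI44L and CCDC80 was greater with vgdCas12a. With dCas12aWT the levels were 0.0739 ± 0.000533 and 0.0488 ± 0.0124 FPKM for IGSF10 and 2.42 ± 0.28 and 2.8 ± 0.492 for EFNB3 with crLacZ and crTet. The effect on S1PR1, ETV1, NCAM2, MALINC1 and PRDM8 was lower, with S1PR1 at 0.391 ± 0.0782 and 0.436 ± 0.0107 FPKM in the dCas12aWT groups. The difference of log2 fold changes was 5.02 ± 0.30 for IGSF10 (adjusted p = 0.000346), 3.86 ± 0.21 for EFNB3 (adjusted p = 0.000346), -3.82 ± 0.23 for S1PR1 (adjusted p = 0.000346) and -1.55 ± 0.17 for MALINC1 (adjusted p = 0.00469). In total 639 genes were called, 511 toward a higher and 128 toward a lower crTet effect with vgdCas12a, 76 and 28 of them by at least 2-fold. With FPKM as deposited the split was 309 and 190. The count was 152 without dCas12aWT crTet replicate 1, 228 without its replicate 2, 132 without dCas12aWT crLacZ replicate 1, 126 without its replicate 2, 124 without vgdCas12a crLacZ replicate 1, 259 without its replicate 2 and 356 without vgdCas12a crTet replicate 2. Of the 27 called genes chosen by rule, CCDC80, CYC1, EFNB3, ETV1, GFP, IFI44L, IGSF10, MALINC1, PLCD4, S1PR1 and UNG stayed called without each library. After correction for gene length and GC content 371 genes were called, 254 and 117 in the 2 directions, and CYC1 was no longer among them.

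In 5 gene lists the crTet effect was more positive with vgdCas12a by camera. Gene length and GC content explained 8.29% of the variance of the interaction, against 0.465% to 4.29% of replicate differences. The lists were not tested after the correction for both. Of 36 ribosome biogenesis factors 7 were called, all upward. Counts were 17 adjusted over the list alone (camera adjusted p = 6.83e-12, adjusted p = 0.338 with an estimated correlation). Of 77 cytosolic ribosomal proteins 4 were called, all upward. Counts were 11 adjusted over the list alone (camera adjusted p = 1.59e-11, adjusted p = 0.721 with an estimated correlation). Of 31 genes of G1/S and DNA replication UNG and MCM7 were called, upward. Counts were 17 adjusted over the list alone (camera adjusted p = 3.06e-08, adjusted p = 0.338 with an estimated correlation). Of 45 respiratory chain genes 5 were called, all upward. Counts were 8 up and 1 down adjusted over the list alone (camera adjusted p = 2.63e-05, adjusted p = 0.721 with an estimated correlation), CYC1, NDUFV1 and NDUFA8 among them. Of 11 fibroblast and mesenchymal markers SPARC, COL5A1 and COL1A1 were called, upward, with the same counts adjusted over the list alone (camera adjusted p = 0.00754, adjusted p = 0.338 with an estimated correlation). The G2/M and mitosis list had 0 of 30 members called, also adjusted over the list alone (camera adjusted p = 0.663), and p53 targets had 1 called upward and 1 downward (camera adjusted p = 0.545). Of the genes named in this paragraph only UNG and CYC1 stayed called without each library, and MCM7, CYC1 and COL1A1 were not called after the length and GC correction.

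**Figure D3:**
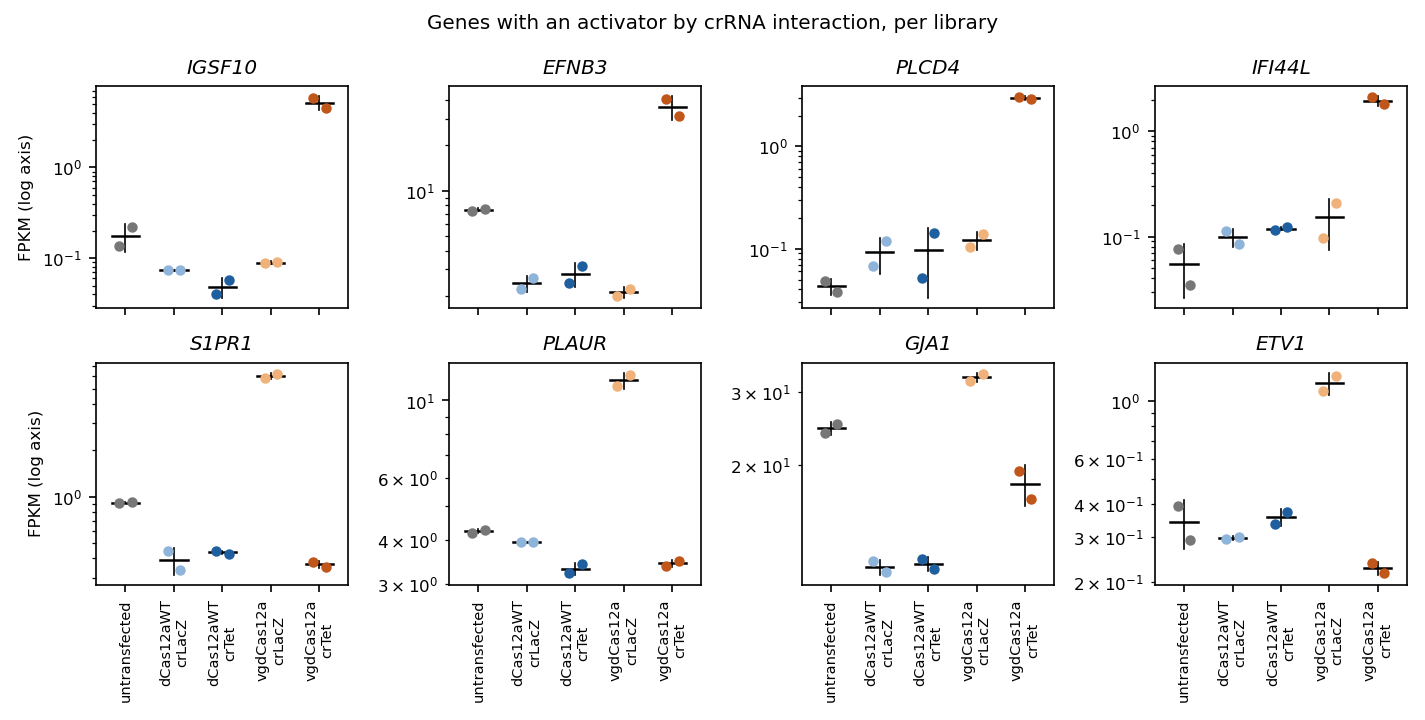
FPKM on log axes for 8 genes in the 10 libraries, with points for libraries, horizontal bars for means and vertical bars for ± SD of 2 libraries. The upper 4 genes are highest with vgdCas12a and crTet (IGSF10 5.15, EFNB3 36.0, PLCD4 2.98, IFI44L 1.95), and the lower 4 with vgdCas12a and crLacZ (S1PR1 6.04, PLAUR 11.4, GJA1 32.5, ETV1 1.17).

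Over both crRNAs, vgdCas12a cells had higher p53 target RNA than dCas12aWT cells. Of 28 p53 targets 13 were higher and 0 lower. Counts were 20 and 1 adjusted over the list alone (camera adjusted p = 3.34e-11, and adjusted p = 0.024 with an estimated correlation). CDKN1A was higher by a log2 fold change of 0.28 ± 0.02 (adjusted p = 0.0011), BTG2 by 0.31 ± 0.03 (adjusted p = 0.0011) and PHLDA3 by 0.36 ± 0.03 (adjusted p = 0.00138). The largest rises among genes with a mean of at least 2 CPM were those of IGSF10, PLCD4, CCDC80, IFI44L and VGLL2, between 2.63 and 1.76. These 5 were called in crTet cells and not in crLacZ cells, so the averages reflect crTet cells. GFP rose by 1.06 ± 0.07 (adjusted p = 0.000318). G0S2, MMP17, SOX18, FZD10 and MYC were lower by -0.88 to -0.52, and MYC by -0.52 ± 0.05 (adjusted p = 0.00123). Other lists called were apoptosis genes, with 4 of 18 higher and 0 lower. Counts were 5 and 0 adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.433 with an estimated correlation), BAK1 and CASP8 among them. Interferon-stimulated genes had 5 of 31 higher and 0 lower. Counts were 9 and 1 adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.433 with an estimated correlation). Immediate early genes had 3 of 27 higher and 1 lower. Counts were 7 and 3 adjusted over the list alone (camera adjusted p = 0.0367 toward higher, adjusted p = 0.433 with an estimated correlation). Histones had H3C1 of 25 higher, also adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.433 with an estimated correlation). G2/M and mitosis had TTK of 30 lower, also adjusted over the list alone (camera adjusted p = 0.0441, adjusted p = 0.433 with an estimated correlation).

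Over both crRNAs 1184 genes were called, 796 higher and 388 lower with vgdCas12a, 54 and 2 of them by at least 2-fold. With DESeq2 on recovered reads the split was 948 and 797. Of the 38 called genes chosen by rule 18 stayed called without each library. The count was 397 without dCas12aWT crTet replicate 1, 505 without its replicate 2, 322 without dCas12aWT crLacZ replicate 1, 375 without its replicate 2, 424 without vgdCas12a crLacZ replicate 1, 347 without its replicate 2 and 613 without vgdCas12a crTet replicate 1. Each of the 5 lists other than p53 targets lost its call without 1 or more libraries: apoptosis genes without replicate 1 of each transfected group, and interferon-stimulated genes without the same 4. The G2/M list lost its call without replicate 1 of dCas12aWT crTet, dCas12aWT crLacZ and vgdCas12a crLacZ and replicate 2 of both vgdCas12a groups. Immediate early genes lost theirs without dCas12aWT crTet replicate 1, dCas12aWT crLacZ replicate 2, vgdCas12a crLacZ replicate 1 and vgdCas12a crTet replicate 2, and histones without dCas12aWT crTet replicate 1 and replicate 2 of every transfected group. RELA differed by 0.02 ± 0.03 (adjusted p = 0.748). Members of lists not called also differed: SLC3A2, PCK2 and SARS1 of the ATF4 list, HSPB1 of the heat shock proteins and PPP1R15A of the unfolded protein response were higher by 0.17 to 0.35, and PDIA3, HSP90B1, INSIG1, HSP90AB1 and HSPD1 lower by -0.24 to -0.12. In these lists 3 members were higher and 0 lower for ATF4, 1 and 2 for heat shock proteins, 1 and 5 for the unfolded protein response and 2 and 2 for cholesterol synthesis.

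Over both activators, crTet cells had higher mitotic and p53 target RNA than crLacZ cells. Of 30 G2/M and mitosis genes 18 were higher and 0 lower. Counts were 27 and 0 adjusted over the list alone (camera adjusted p = 2.06e-21, and adjusted p = 0.0167 with an estimated correlation). Of 28 p53 targets 8 were higher and 0 lower. Counts were 19 and 0 adjusted over the list alone (camera adjusted p = 1.48e-12, and adjusted p = 0.0167 with an estimated correlation). PLK1 was higher by a log2 fold change of 0.20 ± 0.02 (adjusted p = 0.00657), HMMR by 0.31 ± 0.04 (adjusted p = 0.00783), the phosphatase CDC25C by 0.28 ± 0.04 (adjusted p = 0.00721), PPM1D by 0.28 ± 0.03 (adjusted p = 0.00515) and the ribonucleotide reductase RRM2B by 0.23 ± 0.03 (adjusted p = 0.00857). Of 25 histones 6 were higher and 0 lower. Counts were 7 and 0 adjusted over the list alone (camera adjusted p = 1.22e-06, adjusted p = 0.201 with an estimated correlation), with H2BC12 higher by 0.25 ± 0.03 (adjusted p = 0.00866). Of 26 genes of the unfolded protein response CALR and SDF2L1 were lower and 0 higher. Counts were 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0173, adjusted p = 0.6 with an estimated correlation). Of 19 heat shock proteins FKBP4 was lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.6 with an estimated correlation).

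Among genes with a mean of at least 2 CPM, the largest averages over both activators toward higher with crTet were those of GFP, IGSF10, EFNB3, PLCD4 and VGLL2, from 9.12 to 1.62, and toward lower those of S1PR1, KLHL14, PLAUR, ETV1 and RTN4RL1, from -1.78 to -0.86. Of these 10 only GFP was called with dCas12aWT, and the interaction was called for each, so the other averages reflect vgdCas12a cells. In total 932 genes were called, 458 higher and 474 lower, 32 and 6 of them by at least 2-fold. The split moved with the scaling and the correction: it was 430 and 647 with FPKM as deposited, and 491 and 337 after correction for gene length and GC content. Of the 37 called genes chosen by rule 14 stayed called without each library. RRM2B, H2BC12, CALR, SDF2L1, FKBP4, KLHL14, ETV1, RTN4RL1, CCNE2, PCNA, CHAF1A, FOSL1, KLF10, JUNB and NDRG1 did not, and SDF2L1, CHAF1A and JUNB were also not called after the length and GC correction. The count was 208 without dCas12aWT crTet replicate 1, 428 without its replicate 2, 300 without dCas12aWT crLacZ replicate 1, 119 without its replicate 2, 294 without vgdCas12a crLacZ replicate 1 and 214 without its replicate 2. The heat shock list was not called with DESeq2 size factors, nor without replicate 2 of dCas12aWT crTet, replicate 1 of dCas12aWT crLacZ, or replicate 2 of either vgdCas12a group, and the unfolded protein response was not called without replicate 2 of dCas12aWT crTet or of vgdCas12a crTet. RELA differed by -0.10 ± 0.03 (adjusted p = 0.0728). In lists that were not called, G1/S had CCNE2 and PCNA higher by 0.26 and 0.13 and CHAF1A lower by -0.11, immediate early genes had FOSL1 and KLF10 higher by 0.31 and 0.21 and JUNB lower by -0.29, and 3 glycolysis and hypoxia genes were lower, NDRG1 by -0.25, and 0 higher.

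Transfected cells differed from untransfected cells in most genes. The cytokine LIF stood at 0.247 ± 0.0206 FPKM in untransfected cells and at group means of 32.1 to 46 in the 4 transfected groups, the potassium channel KCNN4 at 0.0377 ± 0.0113 and 10.5 to 16.7, and the histone gene H4C8 at 0.645 ± 0.191 and 36.2 to 55.7. RNU6-1, CYP4F2 and TCERG1L-AS1 were listed at 0 in untransfected cells and had group means of 96.3 to 213, 10.0 to 14.8 and 5.07 to 7.03 FPKM in transfected ones. The amino acid transporters SLC7A3, SLC6A9 and SLC7A11 went from 16.6 ± 1.35, 10.3 ± 2.53 and 11.2 ± 2.13 FPKM to group means of 0.587 to 1.17, 0.397 to 0.597 and 0.7 to 0.849. IGFBP5, a binding protein of insulin-like growth factors, went from 7.75 ± 0.17 to 0.372 to 0.475, and G0S2 from 27.3 ± 7.47 to 0.984 to 2.45. Log2 fold changes were 6.64 ± 0.05 for LIF (adjusted p = 6.39e-12), 6.52 ± 0.07 for KCNN4 (adjusted p = 4.21e-11), 5.75 ± 0.13 for H4C8 (adjusted p = 1.25e-09), -4.30 ± 0.24 for SLC7A3 (adjusted p = 2.53e-07) and -4.02 ± 0.12 for IGFBP5 (adjusted p = 6.83e-09). LIF-AS2 and CYP4F3 also rose, by 6.55 and 6.06, and ASNSP1, CHAC1 and ALDH1L2 fell, by -4.19, -4.10 and -3.99. LIF-AS2 overlaps LIF, CYP4F2 and CYP4F3 are similar in sequence, and ASNSP1 is a pseudogene, so the split of their reads is uncertain. The origin of the RNU6-1 reads is uncertain too. RELA rose by 0.33 ± 0.03 (adjusted p = 1.1e-05), from 30.1 ± 0.371 FPKM to group means of 38.9 to 44.2.

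In total 14000 of 18343 genes (76.3%) were called, 6980 higher and 7020 lower in transfected cells, 2413 and 2072 of them by at least 2-fold. The split was 8003 and 5975 with FPKM as deposited, and 7367 and 6651 after correction for gene length and GC content. The median log2 fold change of all genes was 0.015, 0.039 with DESeq2 size factors and 0.129 with FPKM as deposited, and changes are given relative to the TMM scaling. All 85 called genes chosen by rule in this comparison stayed called without each library and after correction for gene length and GC content.

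Transfected cells had higher RNA of p53 targets, histones and mitotic genes. Of 28 p53 targets 26 rose and 1 fell. Counts were 27 and 1 adjusted over the list alone (camera adjusted p = 2.44e-12, and adjusted p = 0.0203 with an estimated correlation). CDKN1A stood at 18.9 ± 0.189 FPKM in untransfected cells and at group means of 122 to 154 in transfected ones (log2 fold change 2.75 ± 0.03, adjusted p = 1.33e-11), BTG2 at 9.64 ± 0.236 and 75.6 to 107 (log2 fold change 3.12 ± 0.03, adjusted p = 1.33e-11) and DDB2 at 12.9 ± 0.761 and 110.0 to 134 (log2 fold change 3.07 ± 0.03, adjusted p = 4.21e-11). Of 25 replication-dependent histones 23 rose and 0 fell. Counts were 24 and 0 adjusted over the list alone (camera adjusted p = 2.34e-08, adjusted p = 0.099 with an estimated correlation), with H2BC12 at 42.7 ± 1.94 and 236 to 286 FPKM and H2AC6 at 2.91 ± 0.147 and 26.4 to 36.3. Copies of these histone genes are similar in sequence. Of 30 G2/M and mitosis genes 27 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.33e-08, adjusted p = 0.0894 with an estimated correlation), with CDC20 at 88.4 ± 5.06 and 269 to 317 FPKM. Of 31 genes of G1/S and DNA replication 21 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0127, adjusted p = 0.513 with an estimated correlation), E2F8 among the former at 6.52 ± 0.202 and 17.2 to 19.4 FPKM. Of 36 ribosome biogenesis factors 21 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0388, adjusted p = 0.684 with an estimated correlation), with RRP12 at 17.1 ± 0.454 and 56.1 to 67 FPKM, and this list was not called without replicate 2 of either vgdCas12a group.

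Of the gene lists, 7 were lower in transfected cells at the preset correlation, and none of the 7 was called with an estimated correlation. Of 30 genes of the ATF4 amino acid response 26 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.88e-08, adjusted p = 0.413 with an estimated correlation). The serine synthesis enzyme PSAT1 stood at 284 ± 30.4 FPKM in untransfected cells and at group means of 39.7 to 45 in transfected ones, and PHGDH of the same pathway had a log2 fold change of -2.93 ± 0.04. Of 77 cytosolic ribosomal proteins 69 fell and 1 rose. Counts were 70 and 2 adjusted over the list alone (camera adjusted p = 2.44e-12, adjusted p = 0.449 with an estimated correlation), with RPL27A at 217 ± 0.489 and 122 to 133 FPKM. Of 31 glycolysis and hypoxia genes 26 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.58e-06, adjusted p = 0.413 with an estimated correlation), with PGK1 at 69.7 ± 5.86 and 26.3 to 29.4 FPKM. Of 45 respiratory chain genes 35 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.39e-06, adjusted p = 0.413 with an estimated correlation). Of 26 genes of the unfolded protein response 22 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 6.74e-06, adjusted p = 0.368 with an estimated correlation). HSPA5 stood at 320.0 ± 23.8 and 92.7 to 118 FPKM, while PPP1R15A, a phosphatase subunit that also responds to ATF4, rose from 21.2 ± 1.64 to 134 to 186. Of 25 genes of cholesterol synthesis 21 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 7.92e-05, adjusted p = 0.0891 with an estimated correlation), INSIG1, which restrains the pathway, from 111 ± 2.74 to 8.42 to 10.7 FPKM. Of 23 NRF2 oxidative stress genes 17 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.368 with an estimated correlation), with TXN at 382 ± 4.44 and 243 to 273 FPKM and AKR1B10 at 0.0455 ± 0.0137 and 1.45 to 1.99.

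The other 11 lists were not called, with members in both directions. Of 27 immediate early genes 15 rose and 8 fell (camera adjusted p = 0.156), MYC from 31.3 ± 0.00722 to 3.06 to 5.09 FPKM and FOSL1 from 1.73 ± 0.293 to 16.6 to 23.2. Of 31 interferon-stimulated genes 15 rose and 8 fell (camera adjusted p = 0.549), and of 11 nucleic acid sensing genes 3 rose and 6 fell (camera adjusted p = 0.697), with a median of -0.20 and a mean of 0.17. CGAS, the cytosolic DNA sensor, was among those that rose, from 0.00465 ± 0.00657 to 0.631 to 0.844 FPKM. Of 11 fibroblast and mesenchymal markers 3 rose and 8 fell (camera adjusted p = 0.203), PDGFRB from 0.0801 ± 0.0241 to 3.23 to 5.35 FPKM and the fibronectin gene FN1 from 10.8 ± 0.0535 to 2.69 to 3.19. Of 10 epithelial markers 4 rose and 2 fell (camera adjusted p = 0.697), the cadherin CDH1 from 4.1 ± 0.236 to 0.427 to 0.576 FPKM, with a median of 0.14 and a mean of -0.08. Of 18 apoptosis genes 9 rose and 8 fell (camera adjusted p = 0.697), with a median of 0.30 and a mean of -0.02. Of 19 heat shock proteins 9 rose and 9 fell. Counts were 9 and 10 adjusted over the list alone (camera adjusted p = 0.727). Of 18 NF-kB targets 6 rose and 4 fell. Counts were 5 and 3 adjusted over the list alone (camera adjusted p = 0.697), and of 13 neuronal and adrenal genes 5 rose and 6 fell (camera adjusted p = 0.849), with a median of 0.12 and a test direction toward lower. Of 8 blood cell markers 3 rose and 3 fell (camera adjusted p = 0.697), and of 10 pluripotency and retinal transcription factors 2 rose and 2 fell. Counts were 1 and 2 adjusted over the list alone (camera adjusted p = 0.849), SOX2 from 3.72 ± 0.115 to 1.42 to 1.84 FPKM, with a median of 0.06 and a mean of -0.07. In the lists without a second pair of counts, those adjusted over the list alone were the same.

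**Figure D4:**
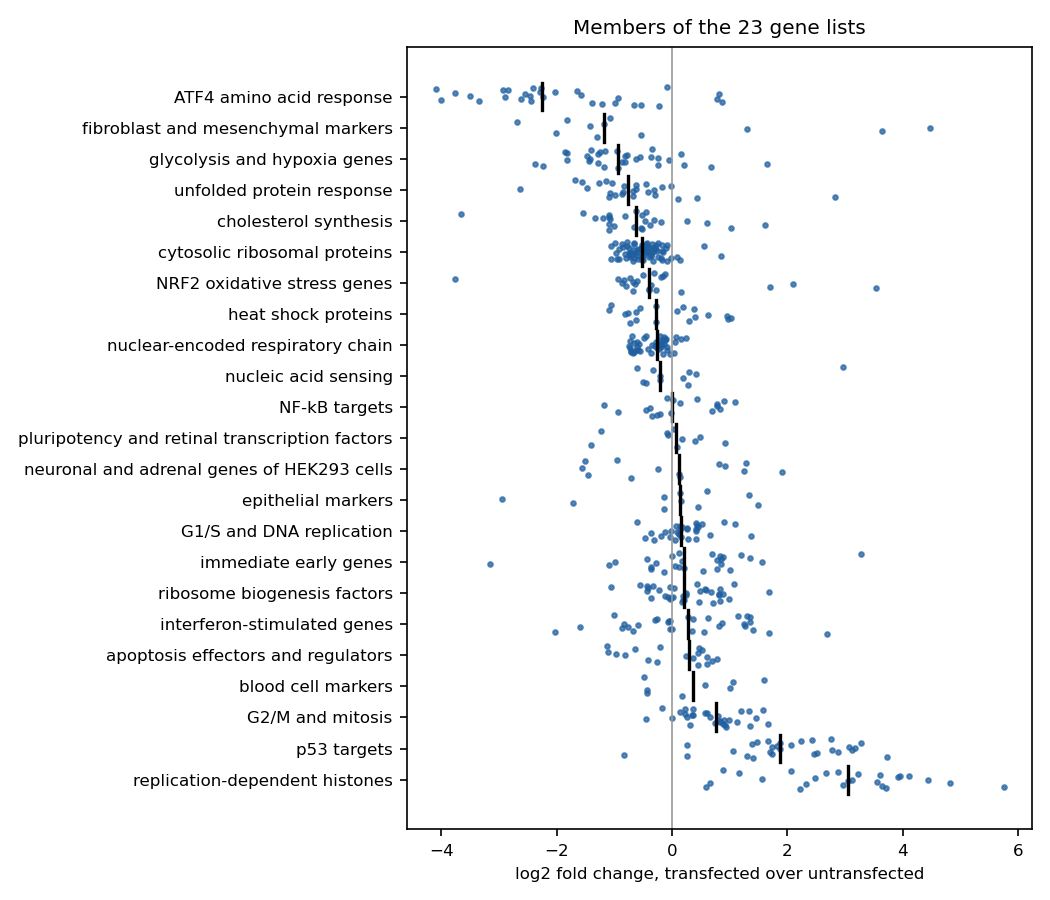
Log2 fold changes, transfected over untransfected, of the members of the 23 gene lists. Each point is a gene and each black bar the median of its list, from -2.26 for the ATF4 amino acid response to 1.87 for p53 targets and 3.05 for replication-dependent histones.

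Across genes, levels in crTet and crLacZ cells were highly correlated with both activators, though single libraries of different groups were less so than replicates. Pearson's r of the group means of log2(CPM + 1), from the recovered reads, over 18343 genes was 0.99752 with dCas12aWT and 0.99585 with vgdCas12a, and 0.99781 and 0.99626 without GFP. Between replicates of a group, r was 0.99762 for crTet and 0.99785 for crLacZ with dCas12aWT, and 0.99697 and 0.99779 with vgdCas12a. Between single libraries of crTet and crLacZ it ran from 0.99629 to 0.99654 with dCas12aWT and from 0.9945 to 0.99458 with vgdCas12a. Genes are not independent replicates, and no test was run on these coefficients. Across genes, the crTet effects with dCas12aWT and with vgdCas12a had an r of 0.1256, and 0.07621 without GFP.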

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

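The tests of the activator alone and of other splits of the libraries were chosen after the result was seen, and so were the extra counts of neighbours. The main test of neighbouring genes was written before its own count was seen. It leaves out IFI44L and IFI44 by name, so it was written with gene calls already known. The effect of crTet differed between dCas12aWT and vgdCas12a cells by a test of the difference itself in 639 genes, listed here as differences of log2 fold changes. Toward a greater effect with vgdCas12a, they were 5.02 for IGSF10, 3.86 for EFNB3, 3.82 for PLCD4, 2.94 for IFI44L, 2.03 for IFI44, 2.75 for CCDC80 and 1.47 for GFP. Toward a lower effect, they were -3.82 for S1PR1, -2.11 for ETV1, -1.73 for NCAM2, -1.55 for MALINC1 and -1.48 for PRDM8. IFI44, NCAM2 and PRDM8 were not called without some single libraries.

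Gene lists differed in the same test. The median difference was 0.14 for cytosolic ribosomal proteins, with 0.36 for RPS9, 0.37 for RPL8 and 0.45 for RPS21. It was 0.21 for ribosome biogenesis factors, with 0.48 for NHP2, 0.27 for NOP14 and 0.43 for BOP1, and 0.11 for the respiratory chain, with 0.45 for CYC1, 0.46 for NDUFV1 and 0.35 for NDUFA8. It was 0.19 for G1/S and DNA replication, with 0.38 for UNG and 0.29 for MCM7, and 0.31 for fibroblast and mesenchymal markers, with 1.11 for SPARC, 1.04 for COL5A1 and 0.62 for COL1A1. None of these 5 lists stayed called with an estimated correlation. Of these genes only UNG and CYC1 stayed called without each library, and NHP2, RPL8, RPS21, CYC1, MCM7 and COL1A1 were not called after correction for gene length and GC content.

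With each crRNA, a set of genes was called and at least 2-fold higher with vgdCas12a than with dCas12aWT, 28 genes with crLacZ and 137 besides GFP with crTet, and 3 genes were in both sets, and the interaction was called in 15 of the 28 and 66 of the 137. If the activator alone raised them, whatever the crRNA, each set would also be higher with the other crRNA, but the crLacZ set, at a median of 1.34 in its own libraries, had 0.16 with crTet, and the crTet set, at 1.44, had 0.16 with crLacZ (median absolute deviations 0.45 and 0.36, with 17 and 93 genes above 0). With the other crRNA, whose libraries took no part in the choice, both sets were thus higher by little. The medians in their own libraries are raised by the choice of the genes, and the interaction counts use the same libraries. The size of the drop therefore does not exclude the activator alone, which stays open above all for genes without a called interaction. Activation of single sites that reaches neighbouring genes may contribute. IFI44L and IFI44 were left out of this test on purpose. Of the 131 other genes of the crTet set that could be placed, 27 had a neighbour called higher. The median in 10000 random draws of genes of like expression was 14 (share as high 0.001). That excess was also there after correction for gene length and GC content (22 of 117 genes against 9, share 4e-04) and among genes higher by less than 2-fold (159 of 894 against 109, share 1e-04, the smallest the draws can give), so it does not single out the strongest genes, but it was not there in lower genes beside lower genes (11 of 361 against 15, share 0.91). Pairs within the crTet set, such as EFNB3 and DNAH2, counted from both sides, and neighbours that change together for another reason were not told apart. No crRNA sequence was compared with the genome here, each crRNA was tested in 2 libraries per activator, and differences between transfections remain an untested explanation.

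A simple fit of the 8 transfected libraries as 4 against 4 called 25 genes for vgdCas12a against dCas12aWT, a count that 1 of the 35 splits reached, the real one, with 1 gene as the highest of the others, so chance could be excluded if single libraries are taken as independent. Only 3 splits keep the replicates of a group together, with 25, 1 and 0 genes, too few for a share under 0.05, so chance differences between groups were not excluded. For crTet against crLacZ the same fit called 1 gene, a count that 3 of the 35 splits reached, and chance could not be excluded for that count. The highest other split, with 25 genes, was the split by activator, a structure of these libraries that this fit leaves in the residual spread. With the groups in the model the crTet average had 932 genes, 870 with only these libraries, and GFP rose with both activators (adjusted p = 4.11e-10 and 9.83e-11).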

How the results depend on the processing

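Results chosen after seeing the data are those of edgeR on recovered reads and the correction for gene length and GC content. The planned main test, edgeR on the deposited counts, was made an alternative after the files were seen. The others were planned, but their form on FPKM values or recovered reads was settled after the files were seen. Counts of genes below are in this order: crTet against crLacZ with dCas12aWT and with vgdCas12a, vgdCas12a against dCas12aWT with crLacZ and with crTet, the interaction, the averages over crRNAs and over activators, and transfected against untransfected, and the main counts were 640, 783, 241, 1421, 639, 1184, 932 and 14000. Of 358 results for single genes chosen by rule 176 kept their call or lack of it in every alternative run, 182 lost or gained a call in at least 1, and 0 reversed. Most calls were lost without single libraries, each left out only in the comparisons that use it: 114 without dCas12aWT crTet replicate 1 and 86 without its replicate 2, 106 and 111 without those of dCas12aWT crLacZ, 85 and 79 without those of vgdCas12a crLacZ, and 50 and 49 without those of vgdCas12a crTet. Without a filter 83 lost their call, with only the libraries compared 81, where 192 others kept theirs and the rest were not run, and after the length and GC correction 49. GFP with crTet was called in every alternative run. With 24827352 to 34473296 assigned reads per library, 59% of simulated changes of 0.5 log2 were recovered, so smaller changes were often missed. Those changes were placed only in genes with higher mean read counts, and recovery in genes with few reads was not tested.

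With no filter on low values, the first 7 comparisons gave 407, 497, 143, 909, 406, 689 and 530 genes, and more genes were then tested. With 1 CPM in 2 libraries, vgdCas12a against dCas12aWT with crLacZ gave 369. With only the libraries compared, which leaves fewer residual degrees of freedom, vgdCas12a crTet against crLacZ gave 173, and vgdCas12a against dCas12aWT gave 138 with crLacZ and 273 with crTet. With a log2 fold change of at least 1 required, the 8 counts were 25, 118, 29, 150, 104, 56, 38 and 4485, fewer by construction. On the recovered reads, limma-voom gave 1518, 1620, 1121, 2138, 1363, 2073 and 1921 in the first 7, and edgeR 1556, 1690, 1149, 2311, 1466, 2138 and 2012. DESeq2 gave 1341, 1297, 900, 1159 and 1608 in the same order, without vgdCas12a against dCas12aWT with crTet, its average over crRNAs and transfected cells. For these tools the cause was not tested. edgeR on the deposited counts gave 367, 228, 73, 405, 223, 311, 382 and 6432, of 9494 genes tested. After the length and GC correction the first comparison gave 179 and the interaction 371.

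Without 1 library at a time, the 8 counts ran from 7 to 103, 150 to 521, 7 to 8, 338 to 936, 124 to 641, 322 to 1257, 119 to 866 and 12495 to 14008. The gene lists called ran from 7 to 9, 8 to 10, 5 to 11, 4 to 6, 5 to 7, 1 to 5, 3 to 8 and 11 to 12, against main counts of 8, 9, 10, 6, 5, 6, 5 and 12. With an estimated correlation, camera called 0, 2, 0, 0, 0, 1, 2 and 1 lists, where the preset correlation called the main counts and fry 2, 7, 6, 3, 3, 5, 4 and 21. The PValue of fry tests whether genes of a list move one way on balance, and does not compare the list with other genes. The medians of called lists kept their sign with DESeq2 size factors and with FPKM as deposited, but some moved by over 1.5 times with the latter. In that case the medians of cytosolic ribosomal proteins went from 0.063 to 0.031 with crTet in vgdCas12a cells and from 0.042 to 0.014 with vgdCas12a in crTet cells. Those of the respiratory chain went from 0.051 to 0.024 with vgdCas12a in crTet cells, from 0.111 to 0.068 in the interaction and from -0.256 to -0.129 in transfected cells. Those of G1/S went from 0.081 to 0.049 with crTet in vgdCas12a cells, from 0.062 to 0.034 with vgdCas12a in crTet cells and from 0.164 to 0.289 in transfected cells, and that of ribosome biogenesis from 0.204 to 0.329 in transfected cells. The calls that held with an estimated correlation were G2/M and p53 targets with crTet in vgdCas12a cells and over both activators, p53 targets with vgdCas12a over both crRNAs, and p53 targets in transfected cells.

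With the replicate number as a block, although the libraries did not pair, vgdCas12a against dCas12aWT with crLacZ gave 137 genes.

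The correlation across genes between crTet and crLacZ means was 0.99752 with dCas12aWT. It was 0.99529 with a pseudocount of 0.1 CPM, 0.99783 with 5 CPM, 0.99881 without a filter and 0.99683 on log2(FPKM + 1), and 0.99682 to 0.99702 without 1 library. With vgdCas12a it was 0.99585, and 0.99276, 0.99656, 0.99808 and 0.99558 in the same order, and 0.99507 to 0.99531 without 1 library. It was lower with vgdCas12a than with dCas12aWT under each of these settings.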

Other observations

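The tests of gene length and GC content, of scaling and of the strand were chosen after the result was seen. Genes of the G2/M and p53 target lists were among those higher with crTet than with crLacZ with both activators. The medians of these lists and of histones were also higher in transfected than in untransfected cells, by 0.768, 1.866 and 3.05 log2. Unequal transfection or selection between the groups was not tested as a source. In all 24 genes were called higher with crTet both with dCas12aWT and with vgdCas12a, and 20 lower with both. Those higher included GFP, the mitotic genes PLK1, CENPE, CDC25C, HMMR, UBE2C and DLGAP5, the p53 targets PPM1D and RRM2B, the histone genes H2BC12 and H2BC15 and the long non-coding RNA PVT1. With dCas12aWT and vgdCas12a the log2 fold changes were 0.22 and 0.18 for PLK1, 0.31 and 0.23 for CENPE, 0.34 and 0.27 for HMMR and 0.25 and 0.30 for PPM1D. Another 21 genes were lower with dCas12aWT and higher with vgdCas12a, and 0 the reverse by limma. These counts rest on single libraries, since without 1 dCas12aWT transfected library at a time only 1 to 6 genes in all were called higher with dCas12aWT. PLK1, CENPE and PPM1D were among those lost there, and CENPE also after correction for gene length and GC content. Both lists come from 1 fit with shared residual variances, so no number expected without a shared response is given.

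More genes were detected in transfected cells. They had FPKM above 0 for 24652 to 25235 genes per library at 24827352 to 30080745 assigned reads, and untransfected cells for 22052 to 22446 at 33600863 to 34473296. At least 1 FPKM was reached by 13100 to 13296 and by 12735 to 12736 genes. The 50 genes with the most reads took 7.60% to 8.60% of the reads in transfected and 10.74% to 10.93% in untransfected libraries. RNU6-1, a U6 gene listed at 0 in untransfected cells, had 96.3 ± 12.8, 171 ± 12.3, 186 ± 18.9 and 213 ± 22.6 FPKM with dCas12aWT and crLacZ, dCas12aWT and crTet, vgdCas12a and crLacZ, and vgdCas12a and crTet. Whether these reads come from the endogenous gene or from transfected sequence was not tested.

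In dCas12aWT cells 508 genes were lower and 132 higher with crTet. Scaling of the libraries does not account for that in the main test, since lower genes outnumbered higher ones by at least 2.62 times under the other scalings, but on recovered reads the split was more even, 969 and 549 with limma-voom, 1026 and 530 with edgeR and 782 and 559 with DESeq2. Gene length and GC content bias may account for part of it: 115 of the 508 stayed called lower after the correction, in a split of 124 lower and 55 higher, their median log2 fold change went from -0.29 to -0.19 with a median SE of 0.05 before and 0.04 after, and 505 stayed below 0, so calls ended because the falls became smaller. Length and GC explained 17.5% of the variance of this comparison, against 0.465% to 4.29% of replicate differences, and the lower genes had a median length of 2094 bases and 59.2% GC, against 3324 bases and 48.8% for all tested genes. A response of short, GC-rich genes to crTet with dCas12aWT would give the same trend and stays open. Length and GC also explained 8.29% of the variance of the interaction and 7.32% of that of crTet over both activators. For vgdCas12a against dCas12aWT with crTet it was 5.73%, and for transfected against untransfected cells 5.58%. In the remaining comparisons it was at most 2.43%. Gene lists were not tested after the correction.

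The deposited counts were at odds with the deposited FPKM: of 12039 genes with at least 1000 reads, 547 (4.5%) had counts within 10% of the reads behind the FPKM and 6549 (54.4%) under 1% of them. In the first untransfected library GAPDH had 0 counts and 89526 reads, and ACRBP 67572 counts and 1 read, while RPS6 had 89405 and 89136. Features counted with an annotation of another genome build may be the source, since genes that agree lie side by side: 72.7% agreed when the previous gene on the chromosome did and 4.6% of all placed genes. Reads counted on the wrong strand cannot be told apart: 4.6% of 4835 genes with none on the other strand agreed, which meets the bound of 5% written for that cause, but all genes agree at 4.5%, so the bound could not separate, a judgement made after the value was seen. No biological explanation was tested, and single genes are reported from the FPKM values alone.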
